A study of Mus musculus with 12 samples.

How the data were processed

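Gene expression was measured in regulatory T cells of 12 mice, 6 of the NOD strain and 6 labelled NOD.Drak2-/-, on 12 arrays of 1 colour. Per the labels' protocols, the cells were isolated by flow cytometric sorting, RNA was extracted with a column kit for small samples, and 125 ng of RNA was made into biotin-labelled, fragmented cDNA with a whole-transcript kit. The protocol names antibodies to CD4, CD8 and CD45RB, while the sample labels also give the cells as positive for CD25. The values used were those of the authors' deposited table, which are on a log2 scale. RMA, which corrects background, normalizes arrays to a common distribution and summarises the probes of a row, and the R package oligo are named in the submitters' processing notes, and the versions are not given in the sources used here. The deposited log2 values ran from 1.49 to 12.8, and the array medians over all rows lay between 4.89 and 5.06. No counts underlie array values, so no depth or counting interval was given, and the number of arrays limits the precision.

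The table held 29129 rows, of which 6923 were control rows and 22206 were transcript cluster rows. The platform annotation gave exactly 1 gene symbol for 19572 rows and several for 0 rows, and 2634 transcript cluster rows were unnamed here and entered no gene-level test. Where a gene had more than 1 row, the row with the highest mean over all arrays was kept, which dropped 67 rows and left 19505 genes. All 19505 symbols were found in a mouse gene table of assembly GRCm38.p6, which was used for names and for the order of genes along a chromosome. The genome build behind the array annotation is not given in the sources used here, so no coordinates were used. No filter on dim genes was applied, and 58.3% of genes had a mean below 5.87, the mean of the brightest of the 23 antigenomic background rows (probes with no target in the genome, 1 row per GC count). Foxp3 had no row named here and was not analysed here.

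Groups came from the labels. NOD.Drak2-/- was compared with NOD by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate, both groups sharing 1 estimate of the spread), with Benjamini-Hochberg adjustment over the 19505 genes and a threshold of an adjusted p of 0.05 with no minimum fold. Every adjusted p of a gene is from that limma fit unless another is named. Differences are log2 values of NOD.Drak2-/- minus NOD. The array labels describe biological replicates from single mice.

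The tests, the rule for named genes, 29 gene lists and most alternatives were set before the data were examined. The rule named Stk17b and the Dapk genes; the 12 largest differences per direction among genes past the threshold, leaving out unnamed gene models; the 5 smallest p-values per direction that missed it where fewer than 5 passed; of each list the members past the threshold, or otherwise the 2 with the smallest p; all gate genes; Ctla4, Icos, Cd28, Stat4 and flanking genes past the threshold; and the brightest gene of each other-cell list. Other genes are named only where the text says that they were chosen after their values were seen. Of 637 distinct list members, 541 were measured. For each list, members past the threshold were counted over all genes and adjusted over the list alone, and the list was set against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 28 lists with at least 4 measured members. The list of mitochondrially encoded genes had too few measured members and was not tested. Camera with an estimated correlation and fry (directional and mixed) were run beside it. Per-array list means, single genes and principal components were compared with a two-sided exact permutation test over all 924 regroupings of the 12 arrays, whose smallest possible p is 0.00216. The 50 measured genes on each side of Stk17b were compared with all other genes by a two-sided Fisher's exact test. The per-array means of the 11 other-cell, gate and quality lists were also correlated with that of the interferon list within each genotype, after the data had been seen. Correlations across the 12 arrays used 100000 permutations and those across 6 arrays all permutations.

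The gene-level and list-level steps were tested on simulated data built on the 19505 genes with the real spread of each gene and noise drawn independently for each gene. The gene-level step had 200 changed genes and the list-level step 1 shifted list. For the comparison of NOD.Drak2-/- with NOD, 22% of genes with a simulated log2 difference of 0.5 were recovered, 90% at 1, 100% at 1.5 and 96% at 2, with 6 unchanged genes among 160 calls. With no change simulated, 0 genes were called. With 1 list shifted, camera called 1 list, the shifted one. Because the noise was independent, the simulation cannot show false list calls that arise where genes vary together. The shares recovered hold for 200 changed genes and may be lower with fewer.

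Alternatives were a replicate block over the 5 replicate numbers that both genotypes share, a repeated quantile normalization, median centring, omission of the dimmest 40% of genes, the mean of a gene's rows, a test of every transcript cluster row, eBayes with trend and robust settings, array weights, the mean of B cell or of myeloid markers as a covariate, an adjusted p of 0.1, a minimum absolute log2 difference of 0.5, an ordinary equal-variance test, omission of each array in turn, windows of 25 and 100 genes around Stk17b, and list medians. After the data had been seen, 2 covariates were added, the mean of the 9 hybridization control rows (spiked bacterial transcripts added before hybridization) and the difference between antigenomic background rows with a GC count of 18 or more and of 10 or less, as was the omission of the 2 arrays with the highest hybridization controls and the myeloid covariate in the set test. The closing section gives their effects. Figures were drawn with matplotlib 3.10.9.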

Results

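Lymph node regulatory T cells, the CD4 T cells that restrain immune responses, were compared by array between NOD mice, a strain that develops autoimmune diabetes spontaneously, and mice of that background labelled NOD.Drak2-/-. Drak2 is the serine/threonine kinase encoded by Stk17b, a member of the death-associated protein kinase family that is known to dampen signalling from the T cell receptor. Per the labels, the cells were CD4-positive, CD8-negative, CD25-positive and low for CD45RB and came from females 4 to 8 weeks old. There were 6 arrays per genotype, numbered 1 to 6 for NOD and 1 to 5 and 7 for NOD.Drak2-/-. Array medians over the 19505 genes tested lay between 5.18 and 5.34 (log2), and Pearson correlations between arrays across genes, which are not independent replicates, lay between 0.968 and 0.991. The design implies 1 comparison, of expression in regulatory T cells with and without an intact Drak2 gene.

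Stk17b itself kept a signal above the brightest background row (5.87) in both genotypes. Its log2 value was 10.52 ± 0.21 (SD, n = 6) in NOD and 10.25 ± 0.15 (SD, n = 6) in the arrays labelled NOD.Drak2-/-. The 6 NOD arrays, replicates 1 to 6, gave 10.66, 10.37, 10.80, 10.62, 10.49 and 10.21, and the 6 arrays labelled NOD.Drak2-/-, replicates 1 to 5 and 7, gave 10.21, 9.97, 10.31, 10.36, 10.34 and 10.33. The log2 difference was -0.27 (95% interval -0.52 to -0.02), with an adjusted p of 0.517 in limma, and a two-sided exact permutation test of the 6 against 6 values gave p = 0.0281, with 6 of 6 arrays labelled NOD.Drak2-/- below the NOD mean. Where the probes of this row lie relative to the deleted part of the gene is not given in the sources used here, and the groups overlap, so the gene does not check the labels of single arrays, and NOD.Drak2-/- below means the arrays labelled so. Of the related kinases, Dapk3 rose when adjusted over the list alone (log2 difference 0.64, above the NOD mean in 6 of 6 arrays, list-alone adjusted p = 0.0325, adjusted p = 0.469 over all genes). Dapk2 differed by -0.21 (adjusted p = 0.694) and Dapk1 by 0.01 (adjusted p = 0.994), a sign that the alternatives turned. Dapk2 (4.89 in NOD and 4.68 in NOD.Drak2-/-) and Dapk1 (4.22 and 4.23) were in the range of the background rows. The list of 4 kinases had a median of -0.10 and a mean of 0.04, so its sign was not settled, and camera gave an adjusted p of 0.948.

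Between the genotypes, 3 genes rose and 1 gene fell in NOD.Drak2-/- regulatory T cells. Abcb1a, which encodes the efflux transporter P-glycoprotein, rose 3.11-fold, from 6.64 ± 0.61 in NOD to 8.28 ± 0.43 (log2, SD, n = 6 per genotype; log2 difference 1.63, SE 0.26, adjusted p = 0.0463 in limma). Trim30d, of the tripartite motif family, rose by a log2 difference of 1.18 (SE 0.18), and Znfx1, a helicase-like sensor of viral RNA, rose by 1.14 (SE 0.17), each with an adjusted p of 0.0463. Islr, a secreted protein with leucine-rich repeats best known from mesenchymal cells, fell by 1.63 on the log2 scale, from 6.42 ± 0.32 to 4.79 ± 0.40 (SE 0.19, adjusted p = 0.00402). The level of Islr in NOD.Drak2-/- and those of Trim30d (5.74) and Znfx1 (5.30) in NOD were in the range of the background rows. In NOD.Drak2-/-, Znfx1 ran from 6.19 to 6.90 and Trim30d from 6.22 to 7.59, and these arrays' own brightest background rows from 5.55 to 6.77. In NOD, Islr ran from 5.97 to 6.80 and those rows from 5.51 to 6.06. The differences of these 3 genes are thus lower bounds only where the higher genotype is clear of background, and the ranges overlapped. For each of these 4 genes the 6 values of one genotype lay wholly above the 6 of the other (exact permutation p = 0.00216, the smallest possible). The genes were picked by their p-values in the same arrays, so this adds no separate support. Of all genes 100 were apart in this way, where 42.2 would be met by chance. Islr passed in each of the 12 fits that left out 1 array, whereas Abcb1a, Trim30d and Znfx1 each passed in 1 of the 12, with adjusted p-values up to 0.166, 0.166 and 0.164. With an ordinary equal-variance test or a replicate block 0 genes passed, so Islr was lost too. With the B cell or the myeloid marker mean as covariate only Islr passed. The fits passed 2 genes without NOD replicate 1, 2 or 6 or NOD.Drak2-/- replicate 1 or 5, and 1 gene, Islr, without NOD replicate 3, 4 or 5 or NOD.Drak2-/- replicate 2, 3, 4 or 7.

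**Figure D1:**
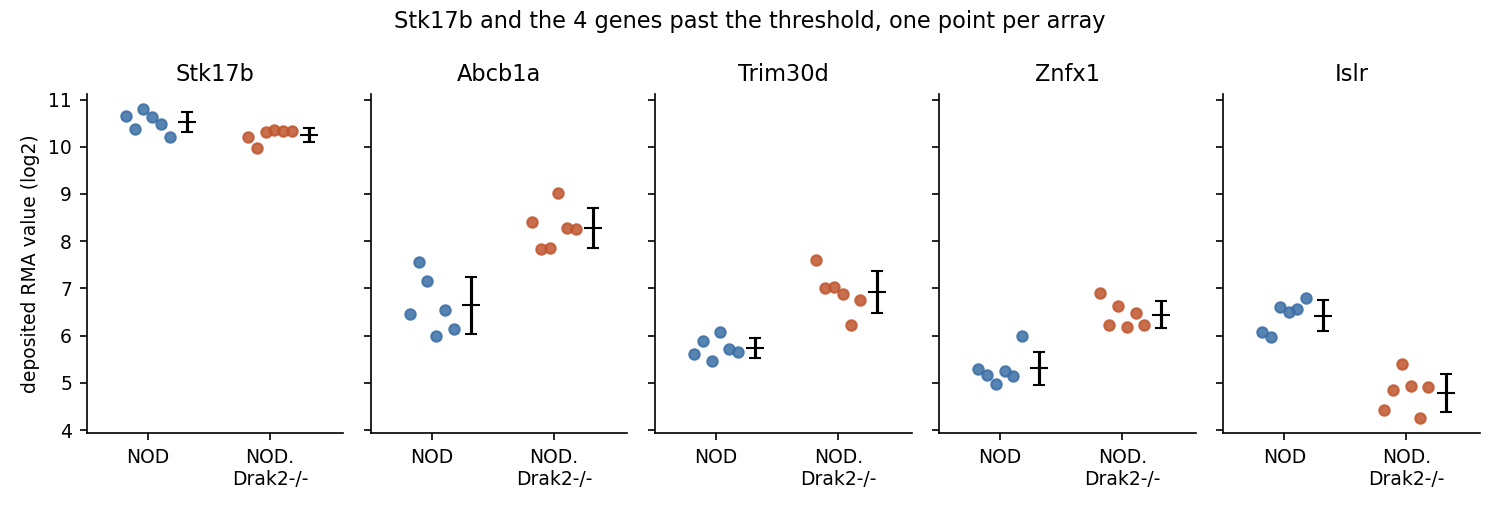
Deposited log2 RMA values of Stk17b, Abcb1a, Trim30d, Znfx1 and Islr, one point per array, for 6 NOD and 6 NOD.Drak2-/- arrays, with the mean and SD beside the points. The genotypes overlap for Stk17b and are fully apart for the other 4 genes, with Islr at 4.79 in NOD.Drak2-/-.

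The genes next in order did not pass. Among those with a positive difference, Nfia, a transcription factor of the nuclear factor I family, differed by 0.84 (adjusted p = 0.211), Rsrp1 by 0.65 (adjusted p = 0.211), and Ifih1, which encodes the viral RNA sensor MDA5, by 0.76 (adjusted p = 0.211). Gm12250 differed by 0.89 (adjusted p = 0.233) and the kinase gene Pak4 by 1.15 (adjusted p = 0.311). Among those with a negative difference, Stra6, the receptor for retinol-binding protein, differed by -1.20 (adjusted p = 0.132), Csrnp1 by -0.73 (adjusted p = 0.191), Adm, the peptide hormone adrenomedullin, by -0.64 (adjusted p = 0.211), Cited1 by -0.55 (adjusted p = 0.261) and Erich5 by -0.47 (adjusted p = 0.332). Adm, Cited1 and Erich5 had means in the range of the background rows. At an unadjusted p under 0.05 there were 1840 genes, 730 with a positive and 1110 with a negative difference, where 975 would be met by chance. Median centring, which moves every difference up by 0.07, turned that split to 1423 and 531, so the split gives no direction. The groups did not overlap for 100 genes, where 42.2 (0.216% of genes) would be met by chance. With the hybridization controls as a covariate 849 genes were at an unadjusted p under 0.05, below the 975. With the GC difference of the background rows as a covariate there were 2597. Both settings were added after the data had been seen. Whether the counts of 1840 and 100 go beyond chance was not tested, so neither shows a broad effect of genotype.

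Interferon-stimulated genes, the antiviral and antigen-processing genes that interferons induce, lay higher in NOD.Drak2-/- as a list. Of 37 measured members 33 had a positive difference, with a median of 0.27 and a mean of 0.28 (log2). Over all genes 0 members passed in limma, with 11 at an unadjusted p under 0.05, all 11 positive, and 4 rose when adjusted over the list alone. These were Ifih1 (log2 difference 0.76, list-alone adjusted p = 0.004), the interferon-signalling brake Usp18 (1.10, 0.00919), the transcription factor subunit Irf9 (0.46, 0.0152) and the immunity-related GTPase Irgm1 (0.79, 0.0309), of which Irf9 and Irgm1 were chosen after their values were seen. Each lay above the NOD mean in 6 of 6 arrays. Camera with the preset correlation gave an adjusted p of 6.26e-09, and the call was lost with an estimated correlation of the genes (adjusted p = 0.427 with an estimated correlation). The fry test gave an adjusted p of 0.296 for a move in one direction and 0.048 for change in either direction. The mean of the list per array was 6.69 ± 0.17 (SD, n = 6) in NOD and 6.97 ± 0.25 (SD, n = 6) in NOD.Drak2-/-, with an exact permutation p of 0.0476 (0.277 after adjustment over the 28 lists). In that test the helper T cell, diabetes-locus and pancreas lists had smaller p-values (0.0325, 0.0216 and 0.0152), also 0.277 after adjustment. By fry in either direction theirs were smaller too (adjusted p = 0.0161, 0.0161 and 0.0121). For the interferon list, NOD.Drak2-/- replicates 1, 2 and 3 gave 7.22, 7.05 and 7.24, and with replicate 4 lay above all 6 NOD arrays. Replicates 5 and 7 gave 6.68 and 6.65, so 4 of 6 lay above the NOD mean. Without NOD replicate 6, NOD.Drak2-/- replicate 5 or NOD.Drak2-/- replicate 7, the members past the threshold over the list alone numbered 11, 8 and 8. These are the highest NOD and the lowest NOD.Drak2-/- arrays of the list mean, so leaving them out favours a higher count. Other omissions gave counts below 4 too, within the range in the closing section. Heat shock and dissociation genes, looked at beside the interferon list after the values were seen, averaged 8.13, 8.14 and 7.98 in NOD.Drak2-/- replicates 1 to 3 and 7.68, 7.75 and 7.80 in replicates 4, 5 and 7. B cell markers averaged 5.18 to 5.55 in the former and 5.00 to 5.15 in the latter, and myeloid and dendritic markers 5.03 to 5.19 and 4.98 to 5.00.

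Cell cycle genes lay lower in NOD.Drak2-/- by the preset camera test. Of 31 measured members 28 had a negative difference, with a median of -0.14 and a mean of -0.20, and camera gave an adjusted p of 0.0297 (adjusted p = 0.697 with an estimated correlation). In limma 0 members passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. The spindle protein gene Nusap1 differed by -0.70 (adjusted p = 0.483) and the microtubule regulator Stmn1 by -0.47 (adjusted p = 0.505). The per-array mean was 7.36 ± 0.33 (SD, n = 6) in NOD and 7.16 ± 0.28 (SD, n = 6) in NOD.Drak2-/-, with an exact permutation p of 0.277. The camera call ended without NOD replicate 1 (adjusted p = 0.145), NOD replicate 4 (0.0942), NOD replicate 6 (0.332), NOD.Drak2-/- replicate 1 (0.344) or NOD.Drak2-/- replicate 2 (0.0662). It also ended with the replicate block (adjusted p = 0.201) and with the myeloid covariate (0.186), the latter added after the data had been seen. The fry test gave an adjusted p of 0.573 in one direction and 0.598 in either direction.

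**Figure D2:**
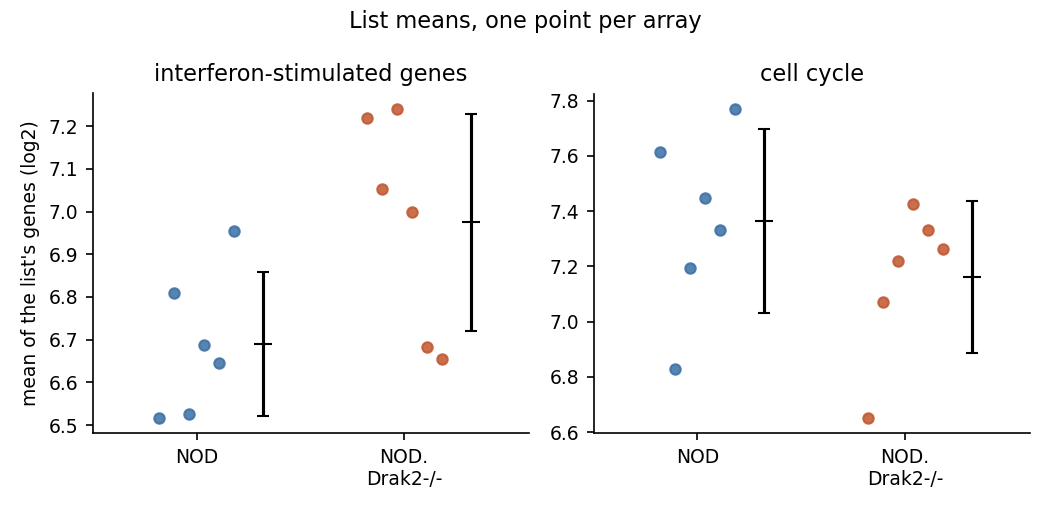
Per-array means (log2) of the 37 interferon-stimulated genes and the 31 cell cycle genes, one point per array, with the group mean and SD beside the points. The interferon list means of NOD.Drak2-/- hold 4 arrays up to 7.24 that lie above all NOD arrays and 2 arrays at 6.65 and 6.68.

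Among genes that T cell receptor signals induce, 3 of 34 fell when adjusted over the list alone. They were the MAP kinase phosphatase genes Dusp4 (log2 difference -0.49, list-alone adjusted p = 0.0276) and Dusp5 (-0.53, 0.0409) and the chemokine gene Xcl1 (-0.42, 0.0436), the last of which was chosen after its values were seen. They lay below the NOD mean in 6, 5 and 6 of 6 arrays. The list as a whole had a median of -0.04 and was not called (camera adjusted p = 0.241). Camera called it down without NOD.Drak2-/- replicate 1 (adjusted p = 0.0114) and with the hybridization controls as a covariate (adjusted p = 0.0179), a setting added after the data had been seen. Both calls were lost with an estimated correlation (adjusted p = 0.586 and adjusted p = 0.694 with an estimated correlation). Looked at after the values were seen, the list averaged 8.34, 8.17 and 8.10 in NOD.Drak2-/- replicates 1 to 3. In replicates 4, 5 and 7 it averaged 7.84, 8.02 and 7.96. The heat shock and dissociation genes, which share Fos and others with this list, were likewise higher in the former. Among helper T cell lineage and cytokine genes, 4 of 27 rose when adjusted over the list alone, each with a list-alone adjusted p of 0.0328. These were the interleukin 23 receptor gene Il23r (log2 difference 0.79), the cytokine genes Il4 (0.45) and Il17f (0.57), and the follicular homing receptor gene Cxcr5 (0.65), with Il17f chosen after its values were seen. They lay above the NOD mean in 6, 6, 6 and 5 of 6 arrays. Over all genes their adjusted p was 0.436, 0.444, 0.469 and 0.469 in limma. Il4 (3.09 in NOD and 3.54 in NOD.Drak2-/-) and Il17f (4.80 and 5.37) were in the range of the background rows in both genotypes. Il23r was in that range in NOD (5.15) and averaged just above it in NOD.Drak2-/- (5.93). Its NOD.Drak2-/- arrays ran from 5.52 to 6.59 and their own brightest background rows from 5.55 to 6.77, so Il23r was not clear of background there. The list had a median of 0.08 and camera gave an adjusted p of 0.101.

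The programmes that define regulatory T cells did not differ by camera, as far as their genes were measured. Foxp3 had no row named here, and Il2ra (4.82 in NOD and 5.00 in NOD.Drak2-/-) was in the range of the background rows. The core signature therefore says nothing of these 2 genes. The core signature (25 genes) had a median of 0.05, a mean of -0.00 and a camera adjusted p of 0.744, camera ranking it up and fry down, with Rgs16 at -0.35 (adjusted p = 0.506) and Swap70 at -0.41 (adjusted p = 0.517). Effector genes (29) had a median of 0.05 and a camera adjusted p of 0.563. The transcription factor gene Nfil3 differed by -0.61 (adjusted p = 0.469) and the granzyme gene Gzma by 0.60 (adjusted p = 0.485) in the background range. Resting genes (18) had a median of 0.08 and a camera adjusted p of 0.30. The interleukin 7 receptor gene Il7r differed by 0.54 (adjusted p = 0.469) and the transcription factor gene Bach2 by -0.31 (adjusted p = 0.493). Of these 3 lists 0 members passed in limma over all genes or over the list alone, with 2, 4 and 2 members at an unadjusted p under 0.05.

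Signalling lists gave a like picture. T cell receptor and calcium signalling components (31 genes) had a median of 0.03 and a camera adjusted p of 0.152. The calcium channel gene Itpr2 differed by 0.41 (adjusted p = 0.47) and Nfatc1 by 0.45 (adjusted p = 0.527). Interleukin 2 and STAT5 response genes (22) had a median of 0.09 and a camera adjusted p of 0.241. Gzmb differed by 0.66 (adjusted p = 0.535) and Xbp1 by 0.20 (adjusted p = 0.606). TGF-beta pathway genes (23) had a median of -0.05 and a camera adjusted p of 0.563, with the repressor gene Skil at -0.27 (adjusted p = 0.485) and Ltbp3 at -0.33 (adjusted p = 0.485). Apoptosis genes (29) had a median of -0.10 and a camera adjusted p of 0.563, with Casp9 at -0.38 (adjusted p = 0.469) and the BH3-only gene Pmaip1 at -0.48 (adjusted p = 0.471). In limma 0 members of these 4 lists passed over all genes or over the list alone, with 2, 0, 5 and 3 at an unadjusted p under 0.05. Ltbp3 and Casp9 were in the range of the background rows.

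Trafficking, cytoskeletal and metabolic genes showed no list call. Trafficking receptors and adhesion genes (25) had a median of 0.05 and a camera adjusted p of 0.35, with the lymph node homing receptor gene Ccr7 at -0.25 (adjusted p = 0.584). Actomyosin and cytoskeleton genes (23) had a median of 0.06 and a camera adjusted p of 0.20, with the actin regulators Was at 0.47 (adjusted p = 0.469) and Ezr at 0.45 (adjusted p = 0.494). Glycolysis genes (18) had a median of 0.00, a mean of -0.01 and a camera adjusted p of 0.58, camera ranking it up, with the hexokinase genes Hk2 at -0.68 (adjusted p = 0.535) and Hk1 at 0.40 (adjusted p = 0.586). Oxidative phosphorylation genes (29) had a median of -0.04 and a camera adjusted p of 0.597, with Sdhb at -0.25 (adjusted p = 0.604) and Ndufa1 at -0.18 (adjusted p = 0.652). In limma 0 members of these 4 lists passed over all genes or over the list alone, with 1, 2, 0 and 0 at an unadjusted p under 0.05, and Hk2 was in the range of the background rows. Over all the lists, 0 of 541 measured members passed in limma over all genes, and the smallest adjusted p was 0.211. An unadjusted p under 0.05 was met by 65 of the 541, beside 1840 of all 19505 genes. Camera called 2 of 28 lists with the preset and 0 with an estimated correlation, and fry called 0 in one direction and 4 in either direction, those of interferon-stimulated, helper T cell, diabetes-locus and pancreas genes. The array medians themselves differed by -0.07 between the genotypes, so list medians nearer to 0 than that, of either sign, have no settled direction.

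**Figure D3:**
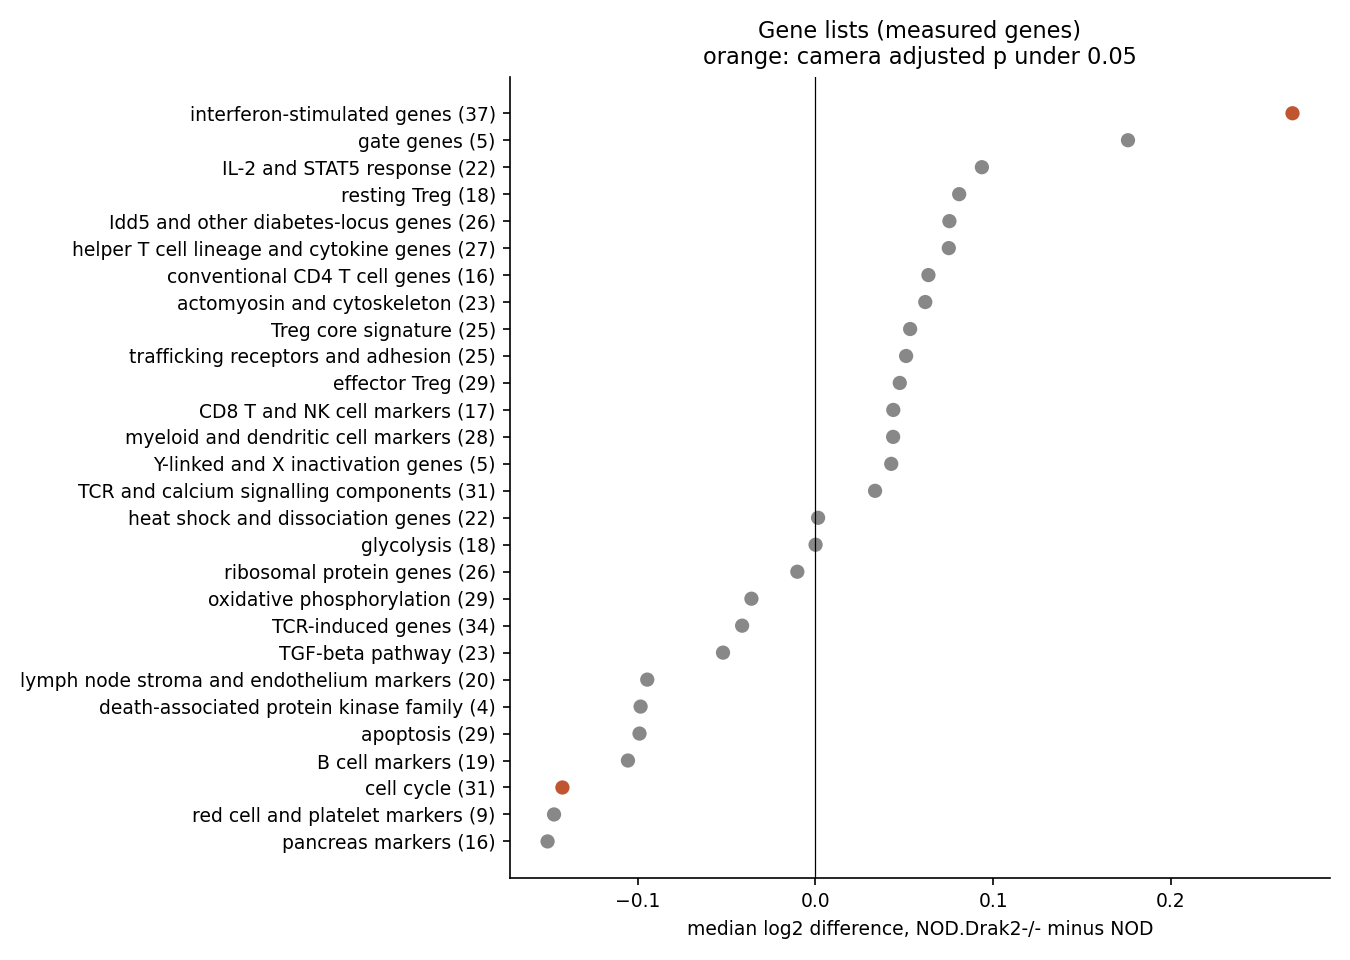
Median log2 difference (NOD.Drak2-/- minus NOD) of the measured genes of each of 28 lists, with the number of measured genes in parentheses. Interferon-stimulated genes at 0.27 and cell cycle genes at -0.14 are the 2 lists that camera called with the preset correlation, and both calls were lost with an estimated one (adjusted p = 0.427 and adjusted p = 0.697 with an estimated correlation).

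The genes around Stk17b on chromosome 1 were compared with all others, which asks whether the segment carried along with the altered gene left its own mark. Of the 100 measured genes flanking Stk17b, 50 on each side in the gene order of assembly GRCm38.p6, 0 passed in limma, against 4 of 19404 other genes, calls too few to show a difference. At an unadjusted p under 0.05 the shares were 7% of flanking and 9.44% of other genes (odds ratio 0.722, 95% interval 0.282 to 1.55, two-sided Fisher's exact p = 0.494). Stat4, within the flank, differed by 0.08 (adjusted p = 0.876). Ctla4, Icos and Cd28, the costimulatory receptor genes that lie 55, 56 and 54 measured genes away, differed by -0.21 (adjusted p = 0.616), -0.09 (adjusted p = 0.859) and 0.05 (adjusted p = 0.925), and the alternatives turned the sign of Cd28. Of 26 diabetes-locus genes 1 rose when adjusted over the list alone, Ifih1 (list-alone adjusted p = 0.00281), and the list had a median of 0.08 and a camera adjusted p of 0.116.

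Genes of other cell types, of the sort gate and of RNA quality were compared as per-array means, and 0 of 11 such lists passed the exact permutation test after adjustment. The smallest adjusted p was 0.167, for 16 pancreas genes (mean 4.35 ± 0.13 in NOD and 4.21 ± 0.06 in NOD.Drak2-/-, unadjusted exact permutation p = 0.0152, the 1 list with an unadjusted p under 0.05), averages within the range of the background rows. The glucagon gene Gcg differed by -0.69 (adjusted p = 0.469), Try5 by -0.40 (adjusted p = 0.469) and Cpa1 by -0.27 (adjusted p = 0.497). B cell markers averaged 5.27 and 5.21 in NOD and NOD.Drak2-/- (adjusted permutation p = 0.72). Cd79b, of the B cell receptor, rose when adjusted over the list alone (log2 difference 0.48, 6 of 6 arrays above the NOD mean, list-alone adjusted p = 0.0408, adjusted p = 0.436 over all genes). Blk differed by -0.30 (adjusted p = 0.481) and H2-Eb1 by 0.10 (adjusted p = 0.909). CD8 T and NK cell markers averaged 4.79 and 4.83 (adjusted permutation p = 0.72). Nkg7, a granule protein gene of cytotoxic cells, fell when adjusted over the list alone (log2 difference -0.67, 6 of 6 arrays below the NOD mean, list-alone adjusted p = 0.0295, adjusted p = 0.429 over all genes). Eomes differed by 0.42 (adjusted p = 0.517) and Ctsw by -0.06 (adjusted p = 0.886). Myeloid and dendritic markers averaged 5.02 and 5.05 (adjusted permutation p = 0.72), with Csf1r at 0.55 (adjusted p = 0.469), Siglech at -0.27 (adjusted p = 0.517) and Cst3 at 0.00 (adjusted p = 0.996). Stroma and endothelium markers averaged 4.32 and 4.28 (adjusted permutation p = 0.72). The follicle chemokine gene Cxcl13 differed by 0.78 (adjusted p = 0.469), Fn1 by 0.37 (adjusted p = 0.515) and Col1a1 by -0.09 (adjusted p = 0.88). The signs of Ctsw, Cst3 and H2-Eb1 turned under some alternatives. Csf1r, Siglech, Cxcl13 and Fn1 were in the range of the background rows.

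Red cell and platelet markers averaged 5.70 in NOD and 5.58 in NOD.Drak2-/- (adjusted permutation p = 0.19), with Slc4a1 at -0.34 (adjusted p = 0.517) and Itga2b at -0.28 (adjusted p = 0.543). Conventional CD4 T cell genes averaged 7.78 and 7.87 (adjusted permutation p = 0.19), with Pde3b at 0.49 (adjusted p = 0.504). Of the gate genes, averaging 7.67 and 7.79 (adjusted permutation p = 0.19), Cd4 was at 9.67 in NOD and 9.87 in NOD.Drak2-/-, and Ptprc, which encodes CD45, at 11.55 and 11.60. Cd8a was at 5.02 and 5.05 and Cd8b1 at 7.27 and 7.45, and the signs of Ptprc and Cd8a turned under some alternatives. Il2ra, which encodes CD25, was at 4.82 and 5.00 in the 2 genotypes, inside the range of the background rows, so its signal cannot show whether the cells carried CD25. Heat shock and dissociation genes averaged 7.89 and 7.91 (adjusted permutation p = 0.887), with Btg2 at 0.36 (adjusted p = 0.47) and Fos at 0.44 (adjusted p = 0.527). Ribosomal protein genes averaged 11.24 and 11.23 (adjusted permutation p = 0.887), with Rpl6 at 0.11 (adjusted p = 0.694) and Rpl7 at -0.10 (adjusted p = 0.768), and camera ranked them up where their mean and median were negative. Y-linked genes averaged 2.63 and 2.69 (adjusted permutation p = 0.429), with Eif2s3y at 0.16 (adjusted p = 0.692) and Zfy1 at 0.11 (adjusted p = 0.805), at the bottom of the signal range in these females.

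Genotype did not separate the arrays on their main axes. The first 3 principal components held 23.2%, 15.4% and 10.1% of the variance, and the genotypes differed on the first with an exact permutation p of 0.0866 (0.26 after adjustment over 3 components), with 0.364 and 0.693 for the others. The first component followed the hybridization controls over the 12 arrays (Pearson r = 0.801, permutation p = 0.0022, adjusted p = 0.0044 over 2 relations; Spearman rho = 0.72, permutation p = 0.0105, adjusted p = 0.021). It did so without the 2 arrays farthest from the median control level (r = 0.642, permutation p = 0.0439). Within NOD r was 0.25 (exact permutation p = 0.624) and within NOD.Drak2-/- 0.876 (exact permutation p = 0.0278). The controls averaged 9.43 ± 0.21 (SD, n = 6) in NOD and 9.91 ± 0.70 (SD, n = 6) in NOD.Drak2-/- (exact permutation p = 0.143). With the controls as a covariate, 2 genes passed in limma, Islr and Gm12250 (log2 difference 1.15, adjusted p = 0.0129), a setting added after the data had been seen.

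**Figure D4:**
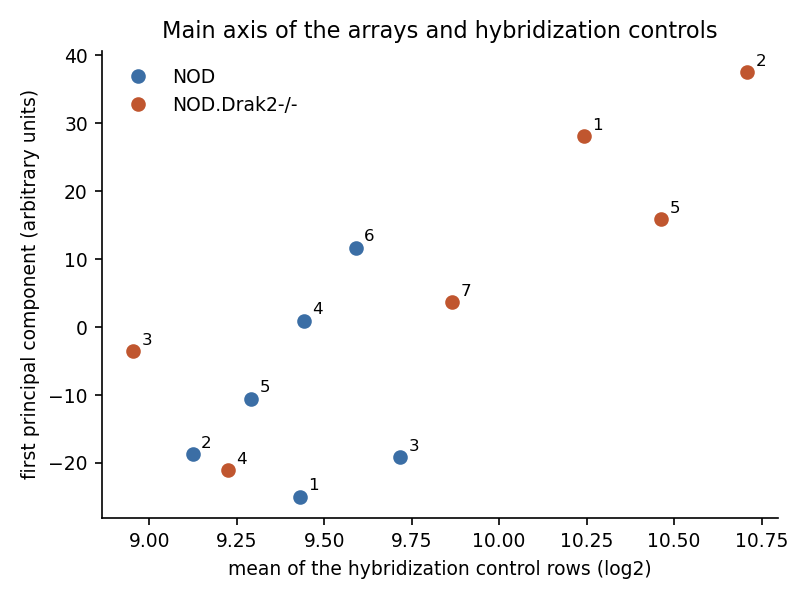
First principal component of the gene values (arbitrary units) against the mean of the hybridization control rows (log2), one point per array with its replicate number, for 6 NOD and 6 NOD.Drak2-/- arrays. The component follows the controls with r = 0.801, and NOD.Drak2-/- replicates 1, 2 and 5 sit at the upper right.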

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

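The tests of Stk17b against background, against a wrong label and against probe position, and those of myeloid cells and of cell stress, were chosen only after the results had been seen. A value was listed for a closer look when 1 array lay far from the other 5 of its genotype, by a test that sets its gap to the nearest other array against the range of the group. Of 240 groups of values tested this way 15 met the rule, where chance flags about 1 in 20 groups, or 12. In NOD replicate 2, Col1a1 was at 7.03 (others 6.50 to 6.68), the stroma and endothelium markers averaged 4.53 (others 4.25 to 4.35), the red cell and platelet markers averaged 5.98 (others 5.59 to 5.71) and the second principal component was at -38.0 (others -5.94 to 6.08). In NOD.Drak2-/- replicate 4, Nfatc1 was at 7.48 (others 8.31 to 8.58), Rpl6 at 11.63 (others 11.76 to 11.83), Cd8a at 4.49 (others 5.07 to 5.25) and the mean of the interleukin 2 and STAT5 response genes at 7.83 (others 7.91 to 7.96). In NOD.Drak2-/- replicate 2, Stk17b was at 9.97 (others 10.21 to 10.36) and Stra6 at 6.39 (others 6.89 to 7.20). In NOD replicate 6, Znfx1 was at 5.99 (others 4.98 to 5.29) and Skil at 8.49 (others 8.78 to 8.91). Gzma was at 5.07 in NOD.Drak2-/- replicate 7 (others 3.49 to 3.88), Xcl1 at 6.18 in NOD replicate 3 (others 6.47 to 6.61), and the B cell markers averaged 5.00 in NOD replicate 4 (others 5.28 to 5.37). These values were left in every result.

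The interferon-stimulated genes averaged 0.28 higher in NOD.Drak2-/- (95% interval 0.01 to 0.56). Hybridization strength and GC-dependent background are argued against as the whole source. With the hybridization controls as a covariate 119% of the difference was left (0.34, 95% interval 0.02 to 0.66), and 134% with the GC difference of the background rows (0.38, 95% interval 0.18 to 0.58). Both covariates were added after the data had been seen, and other sides of array or RNA quality, or a batch, were not tested by them. Beside the mean of the heat shock and dissociation genes 92.9% was left (0.26, 95% interval 0.05 to 0.48). That mean hardly differed between the genotypes (7.89 in NOD and 7.91 in NOD.Drak2-/-), so as a covariate it could take away little. Between mice it ran with the interferon list (r = 0.871 within NOD and 0.65 within NOD.Drak2-/-, neither passing after adjustment). Stress from handling is thus not decided by this test. Chance was not excluded, since 9 of 100 splits of the 12 arrays, the real one included, gave a camera p as small as the real 2.24e-10, and the smallest of the other splits was 1.50e-23. The myeloid and dendritic markers, of which 1 is also in the interferon list, differed by 0.0304 (95% interval -0.08 to 0.14). The upper bound lay under the 0.28 of the interferon list. However, the interferon list minus these markers differed by 0.25 (95% interval -0.00 to 0.51), and the markers average in the range of the background rows. Such cells and a response of the T cells themselves therefore cannot be told apart. An effect of the Drak2 genotype or a difference in exposure or housing between the mice may also underlie the values, and neither was tested.

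The Stk17b signal stayed high in the arrays labelled NOD.Drak2-/-. Loss of the whole transcript is argued against, since the array nearest to its own brightest background row still lay 3.19 above it on the log2 scale. Of these 6 arrays 5 lay inside the range of the NOD arrays, so a wrong label of a single array cannot be told apart from a correct one by this gene. That the probes lie outside the deleted part may be the reason, with probe positions at hand for 0 rows of the gene, and that the mutant transcript is stable without the protein stays open too.

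The first principal component followed the hybridization controls, with r = 0.801 over the 12 arrays. Hybridization strength cannot be told apart from other sources, because the lower of the 2 correlations within a genotype, that in NOD, was 0.25 on 6 arrays. The GC-dependent background may contribute, since its correlation with the component was 0.663 within NOD (exact permutation p = 0.15) and 0.747 within NOD.Drak2-/- (exact permutation p = 0.104), though over all 12 arrays r was 0.411 (permutation p = 0.183 before and after adjustment over 2 relations), rho 0.51 (permutation p = 0.0925) and r 0.127 without the 2 arrays farthest out. Genotype stays open as well, with 38.4% of the difference on the component left beside the controls (20.2 before and 7.77 after, 95% interval -11.0 to 26.5). No batch or scan order is given in the sources used here.

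For the number of genes past the threshold, chance is argued against in the main fit but not excluded. Of the 462 possible splits of the 12 arrays 100 were run, and 1, the real one, gave 4 genes. The highest other gave 1, with 0 genes in 94 of the other splits. Splits were not run for the alternatives, some of which gave 0 genes or 1 gene, counts that other splits reached. For the cell cycle genes chance is not excluded, since 40 of 100 splits gave a camera p as small as the real 0.00212, with 4.92e-25 as the smallest of the others. Of the other splits 61 had at least 2 lists called by camera with the preset correlation and the most was 9. The estimated correlation between genes was 0.314 in the interferon list and 0.439 in the cell cycle list, against the preset 0.01, and what gave the calls in the other splits was not tested.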

How the results depend on the processing

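The covariates from the hybridization controls and the GC difference of the background rows, the omission of the 2 arrays with the highest controls, and the myeloid covariate in the set test were chosen after seeing the data. Where no cause is given below, the cause was not tested. The 4 genes past the threshold remained 4, the same genes, with median centring, dim genes left out, the mean of a gene's rows, trend and robust settings and array weights. An adjusted p of 0.1 or a minimum log2 difference of 0.5 also gave 4. A second quantile normalization gave 3, without Abcb1a. The count was 0 with an ordinary equal-variance test, 1 (Islr) with the B cell or the myeloid marker mean as covariate (adjusted p = 0.0842 and 0.0788 for each of the other 3) and 1 with every transcript cluster row tested. It was 2 with the hybridization controls as covariate, 2 without the 2 arrays with the highest controls and 7 with the GC difference as covariate, of which 3 were shared, and 1 to 2 without 1 array. The differences themselves stayed between 1.49 and 1.82 for Abcb1a, 1.04 and 1.33 for Trim30d, 1.05 and 1.32 for Znfx1, and -1.75 and -1.48 for Islr. The B cell and myeloid marker means lay in the range of the background rows, so these covariates cannot decide whether other cells were the source. Replicate numbers did not pair the mice, since the deviations of arrays with the same number correlated from -0.18 to 0.0865, and a replicate block over the 5 shared numbers, with fewer arrays, gave 0 genes (1519 at an unadjusted p under 0.05).

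List members past the threshold over all genes stayed at 0 except for 1, Usp18, with the GC difference as covariate. Interferon-stimulated members adjusted over the list alone, 4 as reported, numbered 10 with the block, 9 with median centring, 2 with the ordinary test, 15 with the GC difference, 8 without the 2 arrays with the highest controls and 3 to 11 without 1 array. The 2 lists called by camera became 1 with the block or the myeloid covariate, 0 with an estimated correlation, 0 by fry in one direction, 4 by fry in either direction and 1 to 3 without 1 array (1 without NOD replicate 1, 4 or 6 or NOD.Drak2-/- replicate 2, and 3 without NOD replicate 3, with pancreas markers down at an adjusted p of 0.0311). Without NOD.Drak2-/- replicate 1 the count stayed at 2 while the T cell receptor-induced list replaced the cell cycle list (adjusted p = 0.0114), and it was 3 with the hybridization controls as covariate, that list added (adjusted p = 0.0179). With an estimated correlation these added calls were lost (adjusted p = 0.563 for pancreas markers, 0.586 and 0.694 for the T cell receptor-induced list). The adjusted p of the interferon list was 0.427 with an estimated correlation and 0.296 by fry in one direction, and lay between 1.35e-14 and 0.048 under the other alternatives. That of the cell cycle list was 0.201 with the block, 0.186 with the myeloid covariate, 0.697 with an estimated correlation, 0.573 and 0.598 by fry in one and in either direction, and 1.78e-07 (without NOD replicate 2) to 0.344 (without NOD.Drak2-/- replicate 1) without 1 array.

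Stk17b differed by -0.35 to -0.20 under the alternatives, with an adjusted p of 0.234 or more. With 25 or 100 genes on each side of Stk17b, 10% and 8% were at an unadjusted p under 0.05 (Fisher's exact p = 0.809 and 0.545). The other-cell, gate and quality lists past the threshold stayed at 0 with list medians, and the principal components with dim genes left out. For 86 other named genes, 2137 alternative values were computed, of which 2077 stayed on the same side of the threshold, among them 40 uncalled values in 7 genes with the other sign. Of the rest 54, in the 4 called genes, no longer passed, 6 newly passed (Gm12250, Pak4, Stra6, Csrnp1, Usp18 and Thy1) and 0 reversed a call. Signal over background limits the dim genes, since 58.3% of genes had means below the brightest background row.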

Other observations

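The tests of neighbouring genes and of other lists beside the interferon list were chosen only after the results had been seen. Among the 100 genes with the smallest p-values there were 3 pairs of adjacent genes, against a median of 0 and a 95th percentile of 2 in 10000 random sets of 100 genes (share with as many 0.0132). The pairs, chosen after their values were seen, were Abcb1a (log2 difference 1.63) with its paralog Abcb1b (0.98, adjusted p = 0.391), Thy1 (0.99, adjusted p = 0.339) with Usp2 (0.70, adjusted p = 0.393), and Stra6 (-1.20) with Islr (-1.63). Thy1, Usp2, Stra6 and Islr are all on chromosome 9, as is Csrnp1. Trim30d, Pak4 and Adm are all on chromosome 7, and Cited1 and Erich5 are on other chromosomes. These places were looked at after the values were seen and were not set against each chromosome's share of all genes, so they single out no chromosome. Shared regulation of neighbours, sequence shared by paralogs, or a segment inherited from another strain may each give such pairs, and these were not told apart. Only the flank of Stk17b on chromosome 1 was tested for a segment carried along.

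Trim30d and Znfx1 may vary together with the interferon-stimulated genes between mice, a hypothesis tested within each genotype over 6 relations with exact permutation. For Trim30d r was 0.338 in NOD (rho 0.543, permutation p = 0.51, adjusted p = 0.765; 0.722 without the 2 arrays farthest out) and 0.806 in NOD.Drak2-/- (rho 0.886, permutation p = 0.0264, adjusted p = 0.158; 0.638 without 2). For Znfx1 r was 0.765 in NOD (rho 0.371, permutation p = 0.0681, adjusted p = 0.204; 0.735 without 2) and 0.539 in NOD.Drak2-/- (rho 0.486, permutation p = 0.247, adjusted p = 0.494; 0.908 without 2). For Abcb1a r was -0.14 in NOD and -0.165 in NOD.Drak2-/- (adjusted p = 0.785 for each). No relation passed after adjustment, and with 6 arrays per genotype the question stays open.

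Between mice of 1 genotype, the per-array means of the heat shock and dissociation genes followed those of the interferon-stimulated genes in NOD, with r = 0.871 (exact permutation p = 0.025, adjusted p = 0.55 over 22 relations of 11 lists in 2 genotypes; rho 0.943, permutation p = 0.0167, adjusted p = 0.367). Without the 2 arrays farthest out r was 0.803. In NOD.Drak2-/- r was 0.65 (permutation p = 0.214, adjusted p = 0.733, rho 0.543, permutation p = 0.297) and 0.531 without 2 arrays. For the B cell markers r was 0.164 in NOD (permutation p = 0.754, adjusted p = 0.944, rho 0.371) and 0.507 in NOD.Drak2-/- (permutation p = 0.278, adjusted p = 0.733, rho 0.60), and -0.157 and 0.233 without 2 arrays. For the myeloid and dendritic markers r was 0.105 in NOD (permutation p = 0.84, adjusted p = 0.944, rho -0.0286) and 0.643 in NOD.Drak2-/- (permutation p = 0.16, adjusted p = 0.733, rho 0.657), and -0.15 and 0.534 without 2 arrays. Of the 22 relations 0 passed after adjustment and 1 had an unadjusted permutation p under 0.05. The heat shock list shares 0 genes with the interferon list.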
